A study of Homo sapiens with 4 samples.

How the data were processed

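RNA sequencing libraries were made from NUGC3, a human gastric cancer cell line. There were 4 libraries, 2 labelled scramble and 2 labelled as NIPBL knockdown. The knockdown libraries carried different short hairpins against NIPBL, hairpin 1 and hairpin 7, with 1 library each. They are called NIPBL knockdown 1 and 2, in that order, where a replicate is named. All 4 labels hold the letters DOX and the word combined, which they do not explain. The label of scramble 2 is that of scramble 1 with a suffix, which may mark a repeat. Replicate numbers follow the order of the samples and pair nothing. Nothing in the labels says that libraries of a group came from separate cultures, so the p-values of single genes measure only the spread between these libraries, which may be technical.

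The deposited values are FPKM per gene, which is a read abundance scaled to transcript length and library size, made by the authors and given with 2 decimals. STAR, a read aligner, and RSEM, which estimates transcript abundance, are named in the submitters' processing notes without versions. The genome build, the annotation, the strand setting of the library kit and any filters are not given in the sources used here. The table held 344810 rows, of which 291033 had no gene name or biotype. These unnamed rows took between 8.47% and 9.27% of the FPKM of a library and stayed out of the main test. Of 53777 rows with an Ensembl gene identifier, 49860 (92.7%) matched the reference gene table by identifier. Gene symbols and biotypes are those of the deposited table. List members were found by identifier through the reference table, and otherwise by the table's own symbol or an older one. Because RSEM splits reads that fit several genes, the values of near-identical copies are uncertain. That applies to HSPA1A and HSPA1B, KRT6A, HLA genes, ribosomal protein genes, histone genes, zinc finger genes of 1 cluster and the 7SL genes. Overlapping and antisense genes could not be told apart, since the strand setting is not given.

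Summed FPKM was 739335 in scramble 1, 730732 in scramble 2, 749446 with hairpin 1 and 682076 with hairpin 7. FPKM sums do not give sequencing depth, and the low values did not fall on steps of whole reads. The depth is therefore unknown, and no counting intervals or floors are given. A value of 0 is reported only as listed at 0.

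Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend). Genes with a mean of at least 1 FPKM over the 4 libraries entered, 12834 in all, of which 11514 were protein-coding. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The fit had 2 residual and 2.87 prior degrees of freedom. Log2 changes are knockdown minus scramble on the log2(FPKM + 1) scale, which understates the change of low genes. Folds are ratios of mean FPKM. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so none was used for single genes.

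Before the data were examined, 39 gene lists with 1119 entries were fixed, of which 1 entry had no row. Lists with at least 5 tested members, 36 in all, were compared with the other genes by camera in limma with a preset correlation of 0.01. Those p-values were adjusted over the 36 lists. They compare genes with genes, so they do not measure whether a list's change would repeat in other libraries. Camera with a correlation estimated per list, and fry, were alternatives. The correlation and covariance of the hairpins' changes across genes were compared with 100 simulations of unchanged groups that shared the scramble libraries. Genes were also counted as beyond both scramble libraries when both hairpins lay at least 1.5-fold outside them on the log2(FPKM + 1) scale.

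The genes named were set by a rule fixed beforehand. It took NIPBL, TYMS and MYC. It took the 8 protein-coding genes with the highest and the 8 with the lowest log2 change among those with an adjusted p under 0.05 and no overlap between groups. It took up to 4 members with the smallest p of each list described, and the 4 genes per direction that differed most between the hairpins. The values of 2 list members that the rule chose are not reported. Genes named outside the rule are marked as chosen after their values were seen.

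The fits were tested on simulated data for this comparison, with 200 changed genes among 12834 and 10 simulations. The test called 14.5% of genes changed 1.5-fold, 72.7% of those changed 2-fold and 96.5% of those changed 4-fold, with a mean of 10.8 false calls. A simulated list shifted by 0.5 on the log2 scale was found in 10 of 10 simulations with the preset correlation and in 0 of 10 with the estimated one. The simulated genes were drawn independently, with the same spread in both groups. In the data the estimated correlation reached 0.85, for cytosolic ribosomal protein genes. The SD of log2 differences was 0.28 between scramble libraries and 0.45 between hairpins. The simulations therefore do not test the preset correlation, and the false calls hold for equal spread only.

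The alternatives were a pseudocount of 0.1, no filter on low values, a minimum of 5 FPKM, rescaling to TPM, quantile normalization, median centring, eBayes without a trend and robust eBayes. Each library was also left out in turn. Averaging the scramble libraries into 1, testing protein-coding genes only and testing the unnamed rows together with the genes were added after seeing the data. Positions of genes relative to each other come from GENCODE 29 (GRCh38), matched by Ensembl identifier, and no coordinates are given because the build of the deposited table is not given in the sources used here. Figures were drawn with matplotlib 3.10.9.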

Results

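Gene expression was measured by RNA sequencing in NUGC3, a human gastric cancer cell line, after transfection with a scramble control or with short hairpins against NIPBL. NIPBL loads the cohesin ring onto chromosomes. There were 2 scramble libraries and 2 NIPBL knockdown libraries, 1 with hairpin 1 and 1 with hairpin 7. The series concerns MYC, the thymidylate synthase gene TYMS and antifolate drugs. The comparison of these libraries asks which transcripts differ when NIPBL is lowered. Values are the authors' FPKM, summed to between 682076 and 749446 per library, and the read depth is unknown. Between the scramble libraries the SD of the log2 difference over the genes tested was 0.28. It was 0.45 between the hairpins and between 0.50 and 0.56 for a scramble library against a knockdown library.

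NIPBL (ENSG00000164190, chromosome 5 in GENCODE 29) checks the labels, being the gene knocked down. It was at 23.92 and 23.11 FPKM in the scramble libraries, 7.27 FPKM with hairpin 1 and 9.17 FPKM with hairpin 7. The mean fell from 23.5 ± 0.573 to 8.22 ± 1.34 FPKM (SD, n = 2 each), to 35.0% of scramble, with a log2 change of -1.42 ± 0.14 (SE, limma, adjusted p = 0.0218). TYMS (ENSG00000176890, chromosome 18), whose enzyme makes thymidylate, was at 104 ± 2.66 FPKM in scramble and 83.7 ± 14.3 FPKM in knockdown libraries (SD, n = 2 each; log2 change -0.31 ± 0.14, SE, limma, adjusted p = 0.238). MYC (ENSG00000136997, chromosome 8), which encodes a transcription factor that drives growth genes, was at 82.4 ± 0.615 FPKM in scramble and 62.5 ± 21.2 FPKM in knockdown libraries (SD, n = 2 each; log2 change -0.44 ± 0.24, SE, limma, adjusted p = 0.307). TYMS was at 71.1% of the scramble mean with hairpin 1 and 90.6% with hairpin 7. MYC was at 94.0% with hairpin 1 and 57.6% with hairpin 7. TYMS and MYC did not pass the test, while both hairpin values lay below both scramble values for each gene. With NIPBL knockdown 2 left out the adjusted p of TYMS was 0.0217, and with NIPBL knockdown 1 left out that of MYC was 0.0088 (limma), where the lone hairpin library is assumed to vary like the scramble libraries. NIPBL lost its call without scramble 1 (adjusted p = 0.257) or scramble 2 (adjusted p = 0.261), with log2 changes of -1.39 and -1.44.

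**Figure D1:**
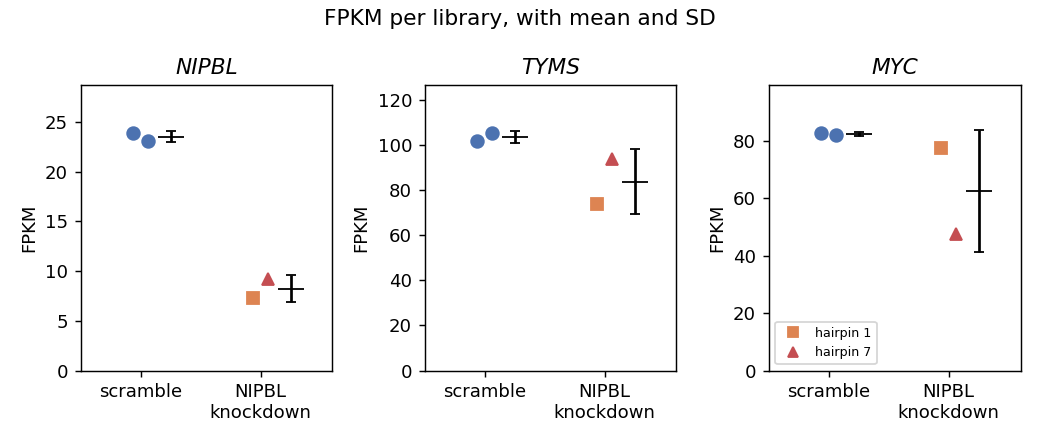
FPKM (linear axis from 0) of NIPBL, TYMS and MYC in each library, with the mean and SD of 2 libraries per group beside the points; squares are hairpin 1 and triangles hairpin 7. NIPBL lies at 7.27 and 9.17 FPKM in the knockdown libraries against 23.92 and 23.11 in scramble, while MYC is at 77.47 FPKM with hairpin 1 and 47.52 with hairpin 7.

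S100P, a calcium-binding protein of epithelial tumours, had the highest log2 change of the protein-coding genes that passed. It rose 14.7-fold, from 7.97 ± 2.32 to 117 ± 42.2 FPKM (SD, n = 2 each; log2 change 3.70 ± 0.31, SE, limma, adjusted p = 0.018). The stress-induced transcription factor gene ATF3 rose 11.8-fold, from 15.1 ± 0.417 to 178 ± 2.57 FPKM (SD, n = 2 each; log2 change 3.48 ± 0.09, SE, limma, adjusted p = 0.00358). ID3 and ID2, which encode inhibitors of helix-loop-helix factors, rose by 3.29 ± 0.14 and 3.07 ± 0.28 on the log2 scale (SE). RRAD, a GTPase gene, rose by 3.30 ± 0.12, the phosphatase gene DUSP1 by 2.96 ± 0.09, PRR9 by 2.81 ± 0.32 and SYT8 by 2.79 ± 0.27. The adjusted p values of these 6 genes lay between 0.00536 for DUSP1 and 0.0311 for PRR9 (limma).

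IGFBP5, a binding protein of insulin-like growth factors, fell from 246 ± 0.834 to 13.8 ± 3.26 FPKM (SD, n = 2 each), or 17.8-fold, with a log2 change of -4.08 ± 0.17 (SE, limma, adjusted p = 0.00609). The basal epithelial keratin genes KRT5 and KRT6A fell 8.03-fold and 7.67-fold, with log2 changes of -2.64 ± 0.12 and -2.63 ± 0.14. The activin antagonist gene FST had a log2 change of -2.57 ± 0.30, LYPD5 of -2.45 ± 0.19, the pentraxin gene PTX3 of -2.15 ± 0.13 and SERPINB2, a plasminogen activator inhibitor gene, of -2.14 ± 0.12. Each of these 6 genes fell at an adjusted p between 0.00718 for KRT5 and 0.0334 for FST (limma). AL136218.1, annotated as protein-coding, was at 20.97 and 11.98 FPKM in the scramble libraries and listed at 0 with both hairpins (limma, adjusted p = 0.0126).

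In all, 328 of 12834 genes passed, 186 higher and 142 lower (limma, adjusted p under 0.05). Among protein-coding genes 169 were higher and 126 lower. Of the 328 genes, 117 rose and 92 fell at least 2-fold on the log2(FPKM + 1) scale, and the smallest absolute log2 change among them was 0.58. At an unadjusted p under 0.05 there were 3390 genes. The calls rest on both scramble libraries. In all 328 genes both knockdown libraries lay on one side of both scramble libraries, so leaving a library out cannot turn a sign. Without scramble 1 limma called 0 genes (1060 at an unadjusted p under 0.05), and without scramble 2 it called 0 (1052 at an unadjusted p under 0.05), so each gene given here as passing lost its call there with its sign kept. Without NIPBL knockdown 1 it called 4532 genes and without NIPBL knockdown 2 it called 2915, and with no filter on low values it called 1 gene.

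A count that needs no test gave 716 genes with both hairpins at least 1.5-fold beyond both scramble libraries, 424 above and 292 below. The other ways of splitting the 4 libraries into pairs gave 31 and 51 such genes. A gene whose groups do not overlap in 1 split overlaps in the others, so these counts are held down and give no chance level. In 60.3% of the genes tested the groups did not overlap, against 33.3% by chance and 20.4% and 18.5% in the other splits. With a knockdown library left out the count was 1912 without NIPBL knockdown 1 and 1371 without NIPBL knockdown 2.

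Genes of cell division were lower together. All 40 tested members of the list for the second growth phase and mitosis had a negative log2 change, with a median of -0.43 (camera, adjusted p = 1.35e-11, and adjusted p = 0.533 with an estimated correlation). In this list 0 members passed over all genes and 30 were lower at an unadjusted p under 0.05, while 21 fell adjusted over the list alone (limma). The cyclin gene CCNA2 had a log2 change of -0.53 ± 0.09, the spindle gene NUSAP1 of -0.60 ± 0.10, the phosphatase gene CDC25B of -0.51 ± 0.10 and the separase gene ESPL1 of -0.52 ± 0.10 (SE), with adjusted p between 0.0611 and 0.0718 (limma). Of 40 DNA replication genes, 2 fell over all genes and 14 fell adjusted over the list alone, with 39 of 40 below 0 and a median of -0.36 (camera, adjusted p = 1.64e-09, and adjusted p = 0.533 with an estimated correlation). The median was -0.48 with hairpin 1 and -0.24 with hairpin 7. MCM6 and MCM3, subunits of the replicative helicase, fell by 0.68 ± 0.09 and 0.58 ± 0.09 on the log2 scale (SE, limma, adjusted p = 0.0409 and 0.0493). The clamp loader genes RFC4 and RFC5 had log2 changes of -0.68 and -0.52 and did not pass.

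Of 30 genes of homologous recombination and the Fanconi pathway 0 passed over all genes (10 lower and 1 higher at an unadjusted p under 0.05), 3 fell adjusted over the list alone, and the median was -0.29 (limma, camera, adjusted p = 0.000395, and adjusted p = 0.651 with an estimated correlation). RAD54L had a log2 change of -0.64, XRCC2 of -0.71, the checkpoint kinase gene CHEK2 of -0.58 and FANCA of -0.46. The median was -0.44 with hairpin 1 and -0.17 with hairpin 7, and the call of this list was lost without NIPBL knockdown 1 (camera, adjusted p = 0.359).

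The MYC target list had 57 tested members, of which 52 lay below 0, with a median log2 change of -0.39 (camera, adjusted p = 2.09e-09, and adjusted p = 0.555 with an estimated correlation). Over all genes 1 member fell and 0 rose, and adjusted over the list alone 16 fell (limma). The member that passed was the cyclin D2 gene CCND2, which fell from 3.71 and 3.06 FPKM to 0.24 and 0.16 FPKM (log2 change -1.87 ± 0.20, SE, limma, adjusted p = 0.0283). The nucleolar genes NOP56 and NCL had log2 changes of -0.83 and -0.61 and the mitochondrial helicase gene SUPV3L1 of -0.61, with adjusted p between 0.0531 and 0.0563 (limma). The list's median was -0.27 with hairpin 1 and -0.57 with hairpin 7. Of the 12 tested genes of the MYC and MAX network 0 passed (0 at an unadjusted p under 0.05, 0 adjusted over the list alone; limma), and the list had a median of 0.01 and a mean of -0.006 (camera, adjusted p = 0.958). MNT had a log2 change of 0.30, MXI1 of 0.24 and ZBTB17 of -0.23.

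Genes that make ribosomes were lower too. Whether the difference between the hairpins would repeat was not tested, since each is 1 library. Of 35 genes of RNA polymerases I and III and ribosome assembly, 2 fell over all genes and 5 adjusted over the list alone, with a median of -0.28 (limma, camera, adjusted p = 4.68e-05, and adjusted p = 0.533 with an estimated correlation). HEATR1, which acts in ribosomal RNA transcription and processing, fell by 1.00 ± 0.13 and the polymerase I subunit gene POLR1E by 0.75 ± 0.11 on the log2 scale (SE, limma, adjusted p = 0.0423 and 0.0459). POLR3G and POLR1B had log2 changes of -0.98 and -0.83 and did not pass. The median of this list was -0.16 with hairpin 1 and -0.38 with hairpin 7. Of 58 cytosolic ribosomal protein genes 55 lay below 0, with a median of -0.24 (-0.09 with hairpin 1, -0.39 with hairpin 7), while 0 passed over all genes or adjusted over the list alone (5 lower at an unadjusted p under 0.05; limma). That list passed camera (adjusted p = 1.23e-05, and adjusted p = 0.734 with an estimated correlation). RPL5 had a log2 change of -0.40, RPL12 of -0.38, RPL9 of -0.35 and RPL32 of -0.34. Of 37 mitochondrial ribosomal protein genes 32 lay below 0, among them MRPS34 at -0.56, MRPS15 at -0.44, MRPS2 at -0.45 and MRPL37 at -0.37. The median of the mitochondrial list was -0.21 (-0.05 with hairpin 1, -0.34 with hairpin 7), and 0 members passed over all genes or adjusted over the list alone (8 lower at an unadjusted p under 0.05; limma, camera, adjusted p = 0.000466, and adjusted p = 0.734 with an estimated correlation). The median of hairpin 7 minus hairpin 1 was also set against 10000 random lists of similar expression. It lay at percentile 0.58 for polymerases and assembly, 0.81 for cytosolic and 0.53 for mitochondrial ribosomal protein genes. Random lists ignore the correlation among a list's genes, so these percentiles do not measure replication.

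Of 15 heat shock chaperone genes 13 lay below 0, with medians of -0.27 with hairpin 1, -0.61 with hairpin 7 and -0.44 over both (camera, adjusted p = 0.000197, and adjusted p = 0.555 with an estimated correlation). Over all genes 0 passed (10 lower at an unadjusted p under 0.05), and adjusted over the list alone 6 fell (limma). HSPA1A was at 281 ± 0.148 FPKM in scramble and 177 ± 21.2 FPKM in knockdown libraries (SD, n = 2 each, limma, adjusted p = 0.0642). Its near copy HSPA1B had a log2 change of -0.71, HSPH1 of -0.54 and the mitochondrial chaperone gene HSPD1 of -0.69. Of 39 nuclear genes of oxidative phosphorylation 34 lay below 0, with a median of -0.13 (-0.007 with hairpin 1, -0.25 with hairpin 7), and 0 passed over all genes or adjusted over the list alone (5 lower at an unadjusted p under 0.05; limma, camera, adjusted p = 0.0112, and adjusted p = 0.756 with an estimated correlation). NDUFA4 had a log2 change of -0.61, UQCRC2 of -0.42, SDHA of -0.42 and UQCRFS1 of -0.27. That list lost its call without NIPBL knockdown 2 (adjusted p = 0.936) and with quantile normalization (adjusted p = 0.0614).

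Folate and thymidylate genes, the pathway that antifolate drugs act on, were lower as a list, with 19 of 25 below 0 and a median of -0.33 (camera, adjusted p = 0.00324, and adjusted p = 0.533 with an estimated correlation). Over all genes 0 passed (13 lower and 2 higher at an unadjusted p under 0.05), and adjusted over the list alone 4 fell and 1 rose (limma). The mitochondrial one-carbon genes MTHFD2, SHMT2 and MTHFD2L had log2 changes of -0.43 ± 0.09, -0.47 ± 0.10 and -1.06 ± 0.24, and MTHFS, which returns folinic acid to the folate pool, of 0.52 ± 0.10 (SE, limma, adjusted p between 0.0682 and 0.0867). Of 24 purine and pyrimidine synthesis genes 19 lay below 0, with a median of -0.33 (camera, adjusted p = 0.000314, and adjusted p = 0.533 with an estimated correlation). Over all genes 0 passed (12 lower and 2 higher at an unadjusted p under 0.05), and adjusted over the list alone 8 fell and 1 rose (limma). PPAT, the first enzyme of purine synthesis, had a log2 change of -0.75, CTPS1 of -0.63, PAICS of -0.47 and ADSS of -0.45. Among 19 drug transporter and fluoropyrimidine genes 1 fell and 0 rose, both over all genes and adjusted over the list alone (limma, camera, adjusted p = 0.626). It was the nucleoside transporter gene SLC29A1, which fell from 40.1 ± 2.04 to 22.6 ± 2.04 FPKM (SD, n = 2 each, limma, adjusted p = 0.0441). CES2 had a log2 change of 0.46, UNG of -0.70 and CES1 of -2.03, none of which passed.

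Interferon-stimulated genes were higher, with 32 of 34 above 0 and a median log2 change of 0.86 (camera, adjusted p = 2.89e-13, and adjusted p = 0.533 with an estimated correlation). Over all genes 9 rose and 0 fell, and adjusted over the list alone 26 rose and 1 fell (limma). IRF9, a subunit of the interferon-activated transcription factor, rose from 9.26 ± 1.23 to 37.6 ± 4.72 FPKM (SD, n = 2 each; log2 change 1.91 ± 0.15, SE, limma, adjusted p = 0.0161). ISG15, a ubiquitin-like modifier, rose by 1.32 ± 0.11, ISG20 by 1.31 ± 0.11 and SAMD9 by 1.53 ± 0.15 on the log2 scale (SE, limma, adjusted p between 0.0183 and 0.0218). The list's median was 1.00 with hairpin 1 and 0.81 with hairpin 7. Antigen presentation genes had a median of 0.16 over 17 members, of which 0 passed over all genes (5 higher at an unadjusted p under 0.05) and 3 rose adjusted over the list alone (limma, camera, adjusted p = 0.0519). TAPBP had a log2 change of 0.60, HLA-F of 0.58 and HLA-C of 0.46.

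Of 31 NF-kB targets and cytokine genes, 3 rose and 1 fell over all genes, and 9 rose and 3 fell adjusted over the list alone (limma). The median was 0.30 with hairpin 1, 0.02 with hairpin 7 and 0.25 over both (camera, adjusted p = 0.0421, and adjusted p = 0.734 with an estimated correlation). The chemokine gene CXCL2 rose from 137 ± 0.311 to 367 ± 45.6 FPKM, the cytokine gene IL6 from 15.8 ± 1.27 to 49.7 ± 11.1 FPKM and the apoptosis inhibitor gene BIRC3 from 44.4 ± 0.163 to 83.9 ± 0.127 FPKM (SD, n = 2 each, limma, adjusted p = 0.019, 0.0304 and 0.0218). TNFAIP2 fell from 192 ± 7.67 to 82.7 ± 10.5 FPKM (SD, n = 2 each, limma, adjusted p = 0.0237). The call of the list was lost without scramble 1 (adjusted p = 0.0628), scramble 2 (0.0688) or NIPBL knockdown 1 (0.797), with the scramble libraries averaged (0.0607) and in the fit without a mean trend (0.0558).

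Lysosome and autophagy genes were higher, with 26 of 27 above 0 and medians of 0.29 with hairpin 1, 0.73 with hairpin 7 and 0.53 over both (camera, adjusted p = 4.86e-08, and adjusted p = 0.533 with an estimated correlation). Over all genes 2 rose, and adjusted over the list alone 11 rose and 0 fell (limma). The protease gene CTSD rose from 134 ± 2.86 to 494 ± 127 FPKM and the autophagy gene WIPI1 from 7.76 ± 0.509 to 17.9 ± 1.38 FPKM (SD, n = 2 each, limma, adjusted p = 0.0255 and 0.0269). The autophagy receptor gene SQSTM1 and GABARAPL1 had log2 changes of 1.30 ± 0.20 and 1.07 ± 0.17 (SE, limma, adjusted p = 0.0529 and 0.0531). Of 21 NRF2 targets and metallothionein genes 4 rose over all genes and 8 rose and 1 fell adjusted over the list alone, with a median of 0.54 (limma, camera, adjusted p = 3.68e-05, and adjusted p = 0.533 with an estimated correlation). Among them, the cystine transporter gene SLC7A11 rose by 0.83 ± 0.10, NQO1 by 0.71 ± 0.09 and the ferritin gene FTL by 0.86 ± 0.12 on the log2 scale (SE, limma, adjusted p between 0.0334 and 0.0425).

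Of 32 hypoxia and glycolysis genes 29 lay above 0, with medians of 0.33 with hairpin 1, 0.66 with hairpin 7 and 0.46 over both (camera, adjusted p = 8.13e-07, and adjusted p = 0.533 with an estimated correlation). Over all genes 1 rose, ANKRD37, by 1.27 ± 0.13 on the log2 scale (SE, limma, adjusted p = 0.0239), and adjusted over the list alone 7 rose and 1 fell. P4HA1 had a log2 change of 1.01 and the glycolytic enzyme gene GPI of 0.53, whereas VEGFA, the angiogenic factor that hypoxia induces, was at -0.48. The 18 tested genes of the mesenchymal program had a median of 0.73 (0.50 with hairpin 1, 0.34 with hairpin 7), with 1 that rose over all genes and 3 that rose adjusted over the list alone (limma, camera, adjusted p = 0.00947, and adjusted p = 0.533 with an estimated correlation). TGFBI, an extracellular matrix gene, rose from 2.77 ± 0.728 to 20.1 ± 0.0778 FPKM (SD, n = 2 each, limma, adjusted p = 0.0123). The fibronectin gene FN1 was at 877 ± 37.2 FPKM in scramble and 3171 ± 1256 FPKM in knockdown libraries (SD, n = 2 each, limma, adjusted p = 0.0544), ITGA5 had a log2 change of 1.58, and the matrix gene TNC was at 5.48 ± 0.58 FPKM in scramble and 18.96 ± 11.5 FPKM in knockdown libraries (SD, n = 2 each).

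Cholesterol and fatty acid synthesis genes differed between the hairpins. Their median log2 change was -0.13 with hairpin 1 and 1.00 with hairpin 7, and the median of 0.41 over both passed camera (31 members, adjusted p = 0.0131, and adjusted p = 0.756 with an estimated correlation). With NIPBL knockdown 2, the hairpin 7 library, left out, the direction reversed and the list did not pass (camera, adjusted p = 0.0751). Whether the difference between the hairpins would repeat was not tested, since each is 1 library. Against 10000 random lists of similar expression, the median of hairpin 7 minus hairpin 1 lay at percentile 100. That compares genes with genes and ignores the correlation among the list's genes. TM7SF2, a sterol reductase gene, was the 1 member that rose, over all genes and adjusted over the list alone (log2 change 1.47 ± 0.17, SE, limma, adjusted p = 0.0334). PMVK had a log2 change of 0.51, FADS1 of -0.44 and FASN of -0.27.

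**Figure D2:**
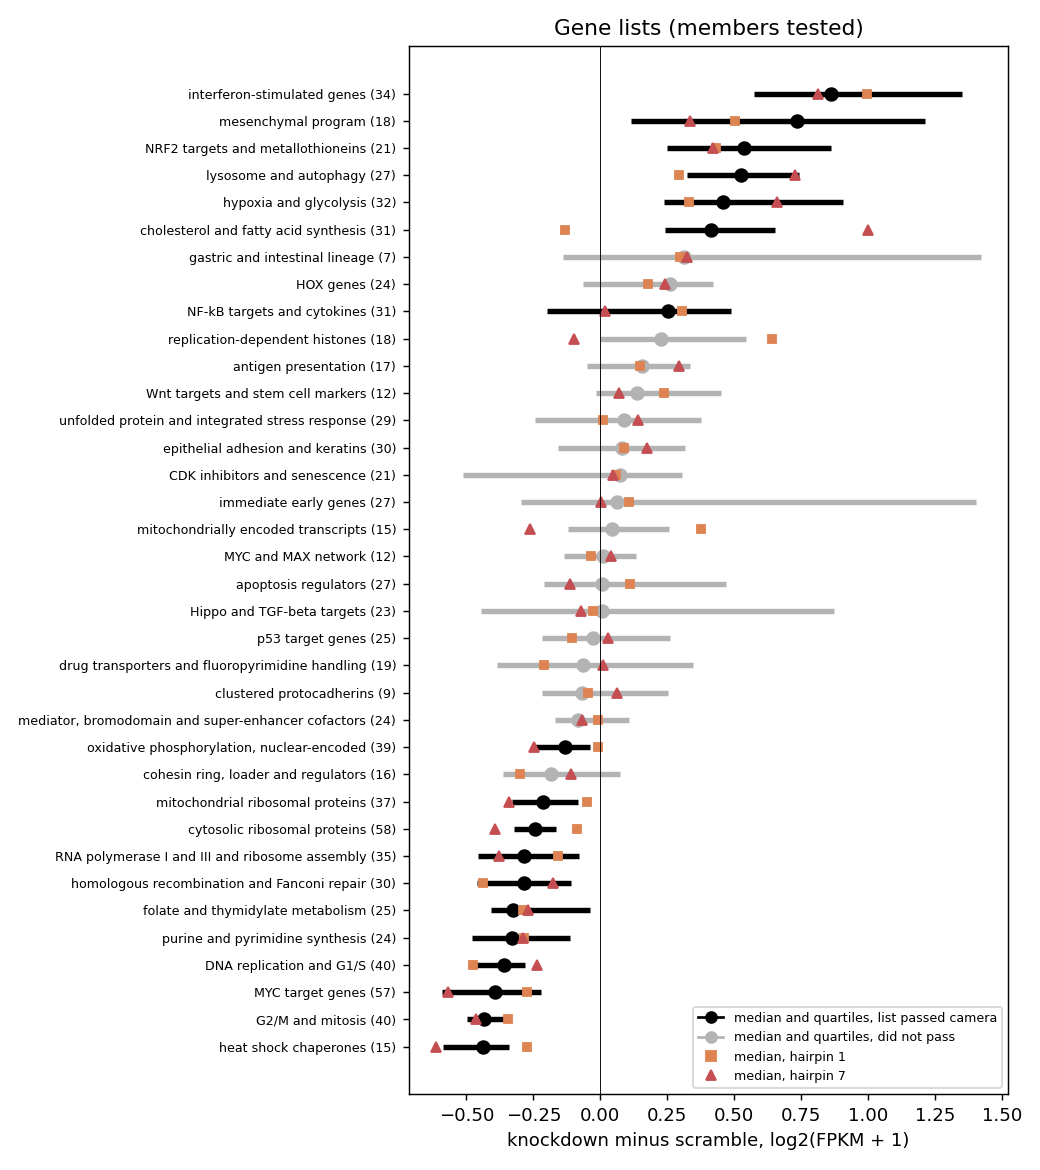
Knockdown minus scramble difference in log2(FPKM + 1) for each tested gene list, with the number of members tested in brackets. Circles and bars are the median and quartiles over members of the mean change, black where the list passed camera at the preset correlation, and squares and triangles are the medians with hairpin 1 and hairpin 7. Interferon-stimulated genes lie farthest to the right at 0.86 and the heat shock chaperones farthest to the left at -0.44, and the cholesterol list spreads from -0.13 to 1.00 between hairpins.

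Immediate early genes went both ways, with 7 that rose and 1 that fell among 27 over all genes, and 10 that rose and 5 that fell adjusted over the list alone (limma). Besides ATF3 and DUSP1, the transcription factor genes FOS and KLF4 rose by 2.45 ± 0.10 and 2.10 ± 0.10 on the log2 scale (SE, limma, adjusted p = 0.00609 and 0.00718). The member that fell was EGR1, chosen after its value was seen, with a log2 change of -1.92 (limma, adjusted p = 0.0112). The list did not pass (camera, adjusted p = 0.0591), though it did without scramble 1 (adjusted p = 0.0123) or scramble 2 (0.00814), with the scramble libraries averaged (0.0084), with quantile normalization (0.0338), at a minimum of 5 FPKM (0.0421) and with fry (0.0392). Among 29 genes of the unfolded protein and integrated stress response 3 rose over all genes, ATF3, PPP1R15A by 0.88 ± 0.09 and SLC7A11, while 6 rose and 1 fell adjusted over the list alone (SE, limma, camera, adjusted p = 0.227, fry, adjusted p = 0.0464). DNAJC3 had a log2 change of 0.50.

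Of 16 cohesin genes 1 rose and 1 fell over all genes, and 1 rose and 4 fell adjusted over the list alone (limma, camera, adjusted p = 0.0734). The gene that fell was NIPBL, and the gene that rose was STAG1, a subunit of the cohesin ring, from 12.4 ± 0.573 to 25.3 ± 3.11 FPKM (SD, n = 2 each, limma, adjusted p = 0.0409). PDS5B and PDS5A, cohesin regulators, had log2 changes of -0.62 ± 0.12 and -0.41 ± 0.09 (SE) and did not pass over all genes. The list passed with no filter on low values (camera, adjusted p = 0.0238), and its median was -0.30 with hairpin 1 and -0.11 with hairpin 7. Because NIPBL is a member, part of the downward shift is built in, and the list was not tested without it. Among 24 Mediator, bromodomain and enhancer cofactor genes 0 passed over all genes or adjusted over the list alone (1 higher and 1 lower at an unadjusted p under 0.05; limma, camera, adjusted p = 0.773). CCNC had a log2 change of -0.42, CREBBP of 0.29, MED31 of 0.22 and BRD2 of -0.40.

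Among 25 p53 targets 2 rose and 1 fell over all genes, and 3 rose and 2 fell adjusted over the list alone, while the list did not pass (limma, camera, adjusted p = 0.93), with a median of -0.03 and a mean of 0.11. The cell cycle inhibitor gene CDKN1A rose from 16.8 ± 1.17 to 83.9 ± 24.2 FPKM and TP53I3 from 4.65 ± 0.7 to 19.9 ± 2.45 FPKM, and the kinase gene PLK2 fell from 230 ± 4.65 to 127 ± 13.5 FPKM (SD, n = 2 each, limma, adjusted p = 0.0218, 0.0174 and 0.0409). BBC3, which promotes apoptosis, had a log2 change of 0.86. In the list of CDK inhibitors and senescence genes, 1 of 21 rose (CDKN1A) and 2 fell (IGFBP5 and SERPINE2), and adjusted over the list alone 2 rose and 4 fell (limma). Its median was 0.07, its mean -0.15 and its camera direction downward (adjusted p = 0.974), while fry passed it downward (adjusted p = 0.0281), and CDKN1C had a log2 change of -0.59. Among 27 apoptosis regulators 1 rose (BIRC3) and 0 fell over all genes, and 6 rose and 5 fell adjusted over the list alone (limma, camera, adjusted p = 0.609). CASP9 had a log2 change of 0.71 and CASP8 of 0.52.

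Hippo and TGF-beta targets split, with 3 that rose and 3 that fell among 23 over all genes and 7 and 6 adjusted over the list alone (limma, camera, adjusted p = 0.918). ID3, ID2 and PMEPA1 rose, the last by 1.31 ± 0.14 on the log2 scale (SE, limma, adjusted p = 0.0269). The endothelin gene EDN1 fell from 40.9 ± 2.04 to 8.75 ± 1.08 FPKM (SD, n = 2 each, limma, adjusted p = 0.0101). The remaining genes that fell, ANKRD1 (log2 change -2.06) and CYR61 (-0.78), were chosen after their values were seen. Of 7 gastric and intestinal lineage genes tested, AGR2 and FOXA1 rose by 2.00 ± 0.19 and 1.64 ± 0.23 on the log2 scale (SE, limma, adjusted p = 0.0217 and 0.0444). Adjusted over the list alone 2 rose and 1 fell, FOXA2 had a log2 change of -0.80 and GATA6 of 0.31, and the list did not pass (camera, adjusted p = 0.116).

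Other lists did not pass and had 0 members that passed over all genes (limma). Epithelial adhesion and keratin genes, a list that does not hold KRT5 and KRT6A, had a median of 0.08 over 30 members (8 higher and 3 lower at an unadjusted p under 0.05; 3 rose and 1 fell adjusted over the list alone; camera, adjusted p = 0.119), with CLDN1 at -1.25, KRT19 at 0.63, DSC2 at 0.90 and GRHL2 at 0.63. That list passed with quantile normalization (adjusted p = 0.0319), without NIPBL knockdown 1 (0.0337) and with fry, upward (0.0392). HOX genes had a median of 0.26 over 24 members (6 higher at an unadjusted p under 0.05; 0 adjusted over the list alone; camera, adjusted p = 0.0661), with HOXC10 at 0.47, HOXB8 at 0.70, HOXB7 at 0.46 and HOXC4 at 0.62, and passed at a minimum of 5 FPKM (0.00535). Wnt targets and stem cell markers had a median of 0.14 over 12 members (3 higher and 1 lower at an unadjusted p under 0.05; 2 rose and 1 fell adjusted over the list alone; camera, adjusted p = 0.163), with ALDH1A3 at -0.56, BMI1 at 0.44, SOX9 at 0.51 and HES1 at 1.21 (1.74 with hairpin 1, 0.67 with hairpin 7). Clustered protocadherins had a median of -0.07 and an upward camera direction over 9 members (2 higher and 1 lower at an unadjusted p under 0.05; 0 adjusted over the list alone; camera, adjusted p = 0.985), with PCDHB12 at -0.99, PCDHB2 at 0.32, PCDHA10 at 0.54 and PCDHB8 at 0.25. The antigen presentation list passed with quantile normalization (adjusted p = 0.0319), median centring (0.0497), no filter on low values (0.042) and without NIPBL knockdown 2 (0.0162).

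Replication-dependent histone genes had a median of 0.23 over 18 members (2 higher and 1 lower at an unadjusted p under 0.05; 0 adjusted over the list alone; limma, camera, adjusted p = 0.167). Their medians were 0.64 with hairpin 1 and -0.10 with hairpin 7, and the list passed without NIPBL knockdown 2 (adjusted p = 0.000294). HIST1H1C had a log2 change of 1.16, HIST1H3G of -1.08, HIST1H1E of 0.63 and HIST2H4A of 0.66. Mitochondrially encoded transcripts had a median of 0.04 over 15 members (2 higher at an unadjusted p under 0.05; 0 adjusted over the list alone; limma, camera, adjusted p = 0.474) and passed without NIPBL knockdown 2 (adjusted p = 0.000214). Their medians were 0.38 with hairpin 1 and -0.26 with hairpin 7, with the ribosomal RNA genes MT-RNR1 at 0.75 and MT-RNR2 at 0.70, MT-ND1 at 0.32 and MT-ND3 at 0.37. They made up 10.5% and 9.83% of gene FPKM in the scramble libraries, 12.4% with hairpin 1 and 9.44% with hairpin 7.

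Markers of other cell types were mostly below the filter, with 2 tested members each for fibroblasts, endothelium and leukocytes, too few for camera. The fibroblast markers FBLN1 and COL1A1 had log2 changes of -0.55 and 0.38, the endothelial markers ENG and EGFL7 of -0.48 and 0.16, and the leukocyte markers CD68 and LAPTM5 of 1.19 and 0.68. LAPTM5 was at 0.70 and 0.62 FPKM in scramble, 3.71 with hairpin 1 and 0.50 with hairpin 7, so its sign turns without NIPBL knockdown 1 (log2 change -0.15). CD68, also a lysosomal protein gene, had an adjusted p of 0.0528 over all genes and rose adjusted over the list alone (limma). EGFL7 had a log2 change of -0.55 without NIPBL knockdown 1.

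Of the 18 lists that passed camera at the preset correlation, 7 higher and 11 lower, 0 passed with an estimated correlation, with adjusted p between 0.533 and 0.756 (1 of all 36 lists at an unadjusted p under 0.05). The estimated setting also found 0 of 10 simulated shifted lists, so it cannot decide whether a list changed. NRF2 targets went from an adjusted p of 3.68e-05 to 0.533 (camera), though their estimated correlation of 0.017 was close to the preset 0.01. The preset p-values compare genes with genes and do not measure replication between libraries. Fry, which asks whether a list's genes move one way on balance, passed 5 of the 18. They were the folate and purine lists, mitosis, the mesenchymal program and NRF2 targets. The other 13 did not pass fry, among them interferon-stimulated genes (adjusted p = 0.063), lysosome genes (0.119), MYC targets (0.126) and DNA replication (0.126). Fry also passed 4 lists that camera did not, so 9 of 36 in all, and 28 when a list's genes may move either way.

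The hairpins were compared gene by gene. Across 12834 genes the changes with hairpin 1 and hairpin 7 had a Pearson r of 0.619, against 0.331 ± 0.027 (SD of 100 simulations) for unchanged groups that share the scramble libraries. The simulation gave all libraries the same spread. In the data the SD of log2 differences was 0.28 between scramble libraries and 0.45 between hairpins, so the simulated r is not exact for them. Genes are not independent replicates. The covariance was 0.163 against a simulated 0.0213, a difference of 0.141. At least 1.5-fold higher were 1013 genes with hairpin 1 and 1292 with hairpin 7, 552 of them with both, against 102 for independent lists. At least 1.5-fold lower were 768 and 1072 genes, 376 of them with both, against 64.2, and 44 genes went in opposite directions. With a different scramble library for each hairpin, so that no control library is shared, r was 0.51 and 0.498 for the 2 pairings. If scramble 2 repeats scramble 1, a trait of their common culture would still enter both changes and raise r. The counts of genes that moved with both hairpins use the same scramble mean, so part of their excess may come from it.

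**Figure D3:**
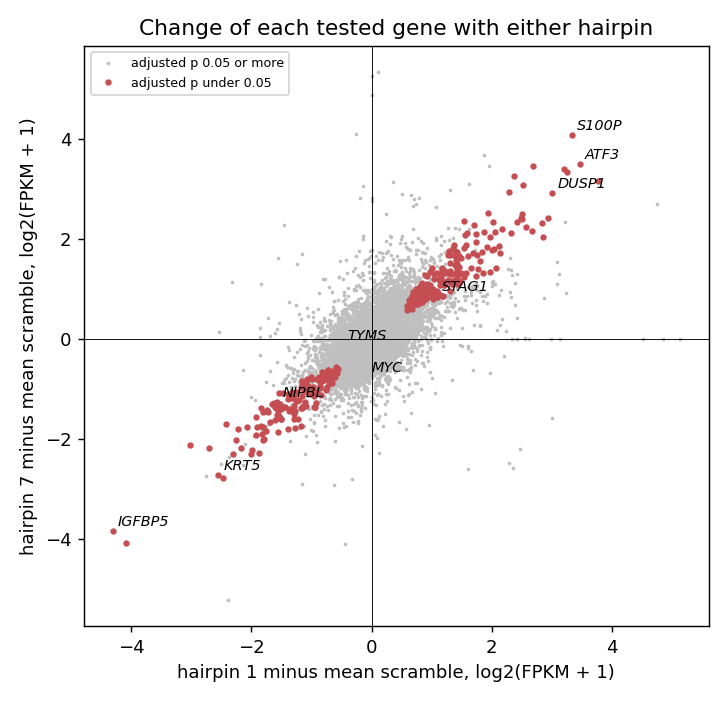
Each point is 1 of 12834 tested genes, with its hairpin 1 (x) and hairpin 7 (y) difference from the mean of the scramble libraries in log2(FPKM + 1); red points are the 328 genes with an adjusted p under 0.05. The red points lie near the diagonal, ATF3 at 3.46 and 3.49 and IGFBP5 at -4.31 and -3.85, whereas MYC lies at -0.09 and -0.78.

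Genes that differed most between the hairpins were mostly rows listed at 0 in some libraries and above 25 FPKM in others. RP4-616B8.4 and CTB-79E8.3 were at 37.19 and 28.33 FPKM with hairpin 7 and listed at 0 in the other libraries, and RP11-525A16.4 was at 39.15 FPKM with hairpin 7, 0.08 with hairpin 1 and 0 in scramble. SCHIP1 was at 33.33 FPKM with hairpin 7, 0.67 with hairpin 1 and 0.66 and 1.42 in scramble. RP11-193F5.4 and RP11-480I12.2 were at 34.03 and 27.9 FPKM with hairpin 1 and listed at 0 elsewhere. RP1-261G23.7 was at 29.77 FPKM with hairpin 1 and 35.02 in scramble 1, and AC093847.1 at 26.44 FPKM with hairpin 1 and 30.37 in scramble 2, both listed at 0 in the remaining libraries. With 1 library per hairpin these differences were not tested.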

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

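The test of the unnamed rows by themselves, with each library left out in turn, was chosen after the main result was seen. Rows without a gene name or biotype stayed out of the comparisons of genes. Of 6074 such rows with a mean of at least 1 FPKM, 10 were higher and 4 lower in the NIPBL knockdown libraries (limma, adjusted over these rows), and 961 had an unadjusted p under 0.05. Limma called 0 rows without scramble 1 (478 at an unadjusted p under 0.05), 0 without scramble 2 (436), 0 without NIPBL knockdown 1 (1286) and 0 without NIPBL knockdown 2 (1101). All 14 kept their sign in each of these 4 fits, and no explanation was tested for them. Leaving a library out cannot turn the sign of a row whose groups do not overlap, so the kept signs add little.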

How the results depend on the processing

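The settings with averaged scramble libraries, protein-coding genes only and unnamed rows included were chosen after the data were seen. All 328 genes called kept their sign in each setting in which they were tested. Where a library was left out or averaged this had to hold. In all 328, both knockdown libraries lay on one side of both scramble libraries. Of the 328 genes, 325 were still called with a pseudocount of 0.1, 311 with robust eBayes and 288 with quantile normalization (limma). Only 216 were still called with TPM, 210 without a mean trend and 130 with the unnamed rows included. The count of all calls stayed within 1.5 times with a pseudocount of 0.1 (351), a minimum of 5 FPKM (368), TPM (241), quantile normalization (303), median centring (298), no mean trend (242), robust eBayes (312) and protein-coding genes only (464). It was 1 with no filter (25230 genes tested), 195 with the unnamed rows included and 0 with the scramble libraries averaged, which leaves 1 library there (975 at an unadjusted p under 0.05; limma). Leaving out each library gave between 0 and 4532 calls. In those fits the lone library is assumed to vary like the other group, and the scramble libraries varied less than the hairpins (SD of log2 differences 0.28 and 0.45), so the count follows the group that sets the spread.

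The log2 change of NIPBL stayed between -1.57 and -1.27 with a library left out. Its adjusted p was 0.118 with no filter and 0.281 with averaged scramble libraries, at -1.42 in both. The averaged fit has fewer libraries by construction, and the cause of the former was not tested. TYMS lay between -0.49 and -0.14 and MYC between -0.782 and -0.0887 with a library left out. Genes beyond both scramble libraries numbered 233 at 2-fold, 456 at a minimum of 5 FPKM and between 985 and 1912 with a library left out. Of 36 lists 18 passed, 0 with an estimated correlation and 9 with fry, 5 of these among the 18. The estimated correlation also found 0 of 10 simulated shifted lists, so it does not decide between them. The correlation of the hairpins was 0.593 with a pseudocount of 0.1, 0.578 with no filter, 0.633 at a minimum of 5 FPKM and between 0.64 and 0.65 without a scramble library. The cholesterol list reversed without NIPBL knockdown 2 (adjusted p = 0.0751, against 5.37e-12 without NIPBL knockdown 1). EGFL7 reversed to -0.55 without NIPBL knockdown 1, against 0.88 without NIPBL knockdown 2. The cause of these differences was not tested. Sequencing depth is unknown, so its part in the spread was not analysed here.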

Other observations

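The families, the zinc finger block and the 7SL RNA were chosen after the data were seen, and so were all tests on them. The block was set around the lowest window of 11 neighbouring genes, so its low values are partly selected. It was extended on each side up to the first gene without a zinc finger symbol, so its edges follow gene class. Protein-coding genes that share a symbol stem were grouped into 192 families of at least 8 tested members, and 14 passed camera at the preset correlation, 0 with an estimated one (2 at an unadjusted p under 0.05, and adjusted p = 0.862 for each family named here). The estimated setting found 0 of 10 simulated shifted lists, so it does not decide here. All 20 tested nucleoporin genes (NUP), which build the nuclear pore, lay below 0, with a median log2 change of -0.35 (camera, adjusted p = 0.000185), NUP93 at -0.54 and NUP155 at -0.52. Translation initiation factor genes (EIF) had a median of -0.18, with 45 of 51 below 0 (camera, adjusted p = 0.00252) and 1 member, EIF4A2, that fell by 0.77 ± 0.10 on the log2 scale (SE, limma, adjusted p = 0.0427). The 10 RNA exosome genes (EXOSC) all lay below 0 (median -0.29; camera, adjusted p = 0.0304), as did 12 of 14 genes of mitochondrial protein import (TIMM; median -0.27; camera, adjusted p = 0.0403). The ZNF family was lower too, with 298 of 416 below 0 and a median of -0.17 (camera, adjusted p = 0.000457). This family includes the ZNF genes of the block and was not tested without them. Strong falls were not confined to the block. ZNF283 and ZNF470 lie outside it, with log2 changes of -1.84 and -1.55 (limma, adjusted p = 0.0101 and 0.0112).

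In the other direction, 9 of 11 CHMP genes, which encode subunits of the membrane-cutting ESCRT machinery, lay above 0 (median 0.37; camera, adjusted p = 0.0191). CHMP1B rose by 1.36 ± 0.09 on the log2 scale (SE, limma, adjusted p = 0.0126) and CHMP4C had a log2 change of 0.64. Of 11 COMMD genes 10 lay above 0 (median 0.37; camera, adjusted p = 0.0264), where the readthrough COMMD3-BMI1 shares sequence with COMMD3, and of 13 annexin genes 12 lay above 0 (median 0.34; camera, adjusted p = 0.0498). These families kept their direction under TPM, quantile normalization and median centring, and both hairpins had the same sign of the median in each.

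Zinc finger genes in 1 block of chromosome 19 were lower together. In the order of GENCODE 29, 28 neighbouring tested genes from ZNF565 to ZNF573 all had a negative log2 change, with a median of -1.03 (-0.97 with hairpin 1, -0.99 with hairpin 7). Of these, 15 fell (limma), among them ZNF607 by 1.92, ZNF571 by 1.79 and ZFP30 by 1.62. The 10 flanking genes had a median of -0.05, and 1 of them, PPP1R14A, fell by 1.42 (limma, adjusted p = 0.0423). None of the flanking genes has a zinc finger symbol, so this contrast cannot tell position from gene class. Random placement of lower genes is argued against by shuffled gene orders, where no window of 11 genes was as low as -1.23 (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). A net move of reads to other zinc finger genes is argued against by their summed FPKM. It went from 3624.4 in scramble to 3279.7 in knockdown libraries (a change of -344.6), and that of the block from 454.8 to 208.6 (-246.2). A gain hidden under a fall of the other zinc finger genes is not excluded by these sums. A bias against the class as the whole cause is argued against by a median of -0.065 (SD 0.338) over 230 zinc finger genes on other chromosomes, of which 3 fell, but a weaker effect stays open, since 179 zinc finger genes elsewhere on chromosome 19 had a median of -0.23, 9 of them fell, and 0 of all 437 rose (16 higher at an unadjusted p under 0.05, limma). Loss of the whole stretch with an equal effect on each gene is argued against if the scramble libraries are separate cultures, which is not known. With a different scramble library for each hairpin, the changes of 21 block genes had a Pearson r of 0.835 and 0.889 (one-sided permutation p = 1e-04 in each, the smallest possible). Their SD of 0.599 lies above the 0.164 that the spread within groups gives. If scramble 2 repeats scramble 1, a trait of that culture would raise r and would be missing from that spread. A loss that acts unequally, a difference between the scramble and hairpin cultures and an effect of lower NIPBL stay open, and no biological explanation was tested.

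RNA of the signal recognition particle, 7SL, was lower with both hairpins. RN7SL2 fell from 3202.54 and 4181.14 to 1063.92 and 907.08 FPKM (log2 change -1.90 ± 0.19, SE, limma, adjusted p = 0.0225), and RN7SL1 had a log2 change of -1.68 (limma, adjusted p = 0.0492). Reads moved between the 848 rows named as 7SL copies are argued against by their sum, whose log2 change was -1.82. Less carry-over of RNA without a poly(A) tail cannot be told apart from lower 7SL, since 18 other such RNA rows had a median of -0.38 with an SD of 1.19, SNORD3A being at -3.81 and RMRP at 0.18, while the histone genes had a median of 0.23. Of other RNA polymerase III transcripts, RPPH1 was at 0.07 and RN7SK at -0.37, neither of which passed, and no biological explanation was tested.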
